A study of Rattus norvegicus with 9 samples.

How the data were processed

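Gene expression was measured in skin of 9 Sprague Dawley rats, 4 given carrageenan (CGN), a seaweed polysaccharide used to provoke acute inflammation and pain, and 5 left without it. Per the labels' protocols, CGN was given at 30 mg/kg body weight, paw swelling and pressure pain were tested 3 hours later, and skin was taken 4 hours after CGN. The labels used here give neither the site of injection nor the part of the skin taken, nor the results of the paw tests. For the controls, titled non-treated, no dose, hour of paw tests or hour of harvest was recorded here. Effects of CGN therefore cannot be told apart from those of the injection, handling or paw tests. Total RNA was purified on columns with DNase treatment and turned into biotin-labelled cRNA for 1-colour arrays, per the labels' protocols. Each array stood for a separate animal.

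The deposited values were intensities on a linear scale, produced by the authors with RMA (background correction, normalization between arrays and summary of probes into probe sets), per the submitters' processing notes, which gave no version. The linear scale was checked on the values themselves, which ran from 4.07 to 27404.42 with a median between 16.7 and 17.81 in every sample. The files used here held no detection calls, no probe-level signals and no scan or slide information, so background and hybridisation batch could not be examined. Both deposited tables were compared: 43685 probe sets stood in both, 8 columns matched by name held identical values, and 1 column named only by its group held the values of a single CGN sample. The column names number the CGN samples 1, 2, 3 and 5, whereas the labels number them 1 to 4, and the labels' numbers were used.

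Gene names came from the deposited table, updated through a RefSeq gene table of the rat assembly GRCr8, which was used for names only. Of the probe sets, 9024 were named through a RefSeq accession, 13792 carried a current symbol, 2573 an older symbol that was updated and 2118 a symbol kept as deposited. The other 16178 had no single gene name and stayed out of the gene tests. Where a gene had more than 1 probe set (5850 genes), the probe set with the highest mean over the 9 samples stood for it, which left 19100 genes. For 1171 genes the chosen probe set had a name ending in _x_at or _s_at, a mark of probes that can bind related transcripts. For the named genes Aurkb, Bdnf, Ccnd1, Cebpa, Cry2, Cxcl3, Flt1, Irak2, Mbp, Pdgfra, Prx and Tp63, no other probe set of the gene passed the test, so their changes rest on the chosen probe set. No genome build is named in the sources used here, so no coordinates are given.

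Intensities were converted to log2 without a pseudocount or a filter. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, 2-sided), with Benjamini-Hochberg adjustment over the 19100 genes and a threshold of 0.05 on the adjusted p. Every adjusted p given for a gene comes from this limma fit unless another setting is named. Counts at 2-fold ask in addition for a log2 change of at least 1. The precision is limited by the number of arrays. Fixed at the start were 34 gene lists with 647 different genes, of which 618 were measured. Lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 34 lists, and again with a correlation estimated for each list. The number of members past the threshold was counted with adjustment over all genes and adjusted over the list alone. Changes are given as log2 CGN minus control ± standard error, and mean intensities are geometric means over the samples of a group.

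The genes named in the text follow a rule fixed at the same time. It took the 8 largest rises and the 8 largest falls among genes past the threshold whose groups did not overlap, up to 3 members of each list with the smallest adjusted p, and 10 genes chosen for their known part in inflammation and pain. Genes named outside this rule are said to be so, and some genes that the rule takes are not reported here. The fit was tested on simulated data for this comparison, with 200 of 19100 genes changed: it recovered 40% of those changed by 0.5 on the log2 scale, 78% at 1, 100% at 2 and 98% at 3, and called 3 of 18900 unchanged genes. Errors were drawn independently for each gene, whereas real genes vary together (estimated correlation 0.82 in the skeletal muscle list). The number of false calls therefore does not carry over to these data. Single values were compared with exact permutation tests in Python 3.11.15 with scipy 1.17.1.

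Other settings fixed before the data were examined were quantile normalization, median centring, leaving out the dimmest 30% of genes, the mean of a gene's probe sets, testing all probe sets, limma with trend and robust options, array weights, a plain test without moderation, a replicate block, other fold thresholds, camera with an estimated correlation, fry, and leaving out each sample in turn. Added after the data were seen were the mean log2 value of the skeletal muscle list as a covariate, symbols as deposited, the omission of _x_at and _s_at probe sets, and a block by the column numbers.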

Results

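Skin from 4 CGN-treated rats was compared with skin from 5 untreated rats to find the genes that are higher or lower after CGN treatment, which includes its injection and the paw tests. Across genes, log2 values correlated at r = 0.983 to 0.991 between CGN samples, 0.986 to 0.994 between controls and 0.953 to 0.980 between the groups. On the first principal component, with 65.6% of the variance, controls scored from -41.3 to -33.0 and CGN replicates 2 to 4 from 53.7 to 55.1, with CGN replicate 1 between them at 20.8.

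Cytokine, chemokine and growth factor genes led the rises 4 hours after CGN. Il6, a cytokine that drives the acute-phase response, rose from a mean intensity of 11.6 in controls to 5227 in CGN (log2 change 8.82 ± 0.15, adjusted p = 1.82e-10). Other leading rises were those of the neutrophil attractant Cxcl2 (8.16 ± 0.24), the hyaluronan-binding factor Tnfaip6 (7.37 ± 0.14), the EGF receptor ligand Areg (7.17 ± 0.41), the cytokine Il24 (6.98 ± 0.30), the chemokine Cxcl1 (6.96 ± 0.18) and the soluble pattern receptor Ptx3 (6.22 ± 0.20). Control means were also low for Cxcl2 (15.7), Tnfaip6 (16.1), Areg (9.89) and Il24 (15.5), and without detection calls the size of a rise from such a level is not exact. The 8 largest falls among genes with separate groups were all of skeletal muscle: Myh2 (-4.20 ± 0.82), Tnnc2 (-3.78 ± 0.85), Tnni2 (-3.73 ± 0.86), Myl11 (-3.73 ± 0.85), Myl1 (-3.60 ± 0.81), Ckm (-3.57 ± 0.75), Mb (-3.56 ± 0.69) and Atp2a1 (-3.47 ± 0.70). In total 4243 of 19100 genes passed the limma test, 1665 higher and 2578 lower in CGN, and 1184 of them changed at least 2-fold, 658 higher and 526 lower. At 8-fold or more, 90 genes were higher and 22 lower. The groups did not overlap for 19.1% of all genes, against 1.59% expected by chance for 4 against 5 samples.

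**Figure D1:**
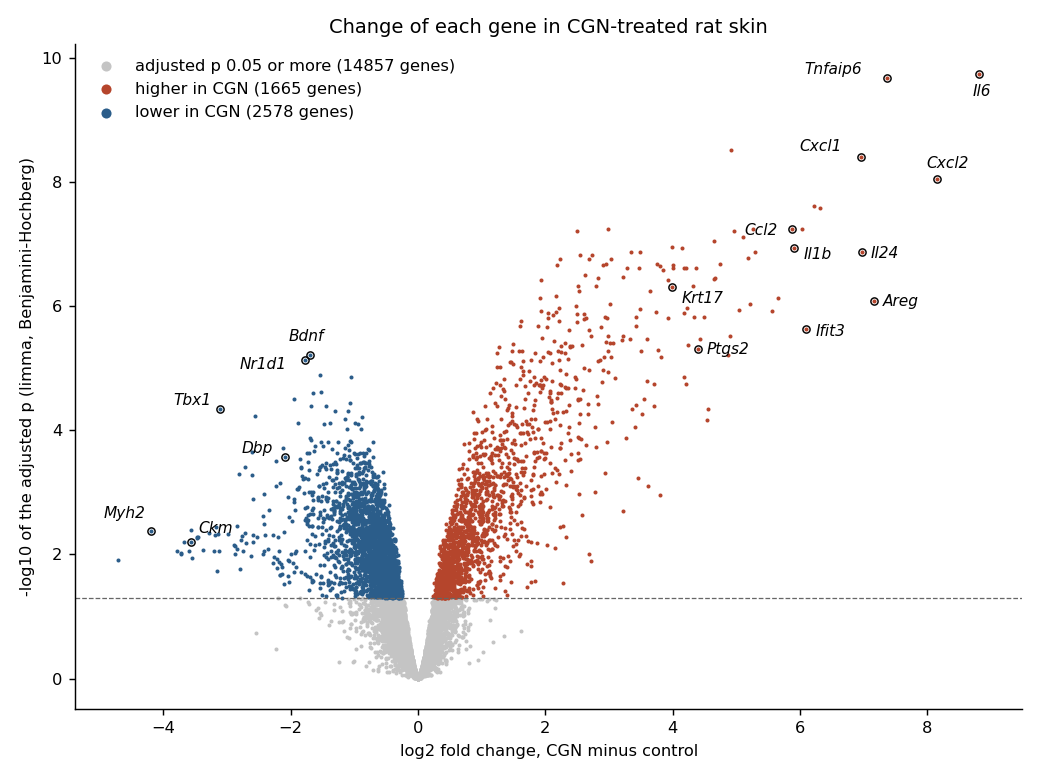
Each point is a gene, with its log2 fold change (CGN minus control) on the x axis and -log10 of its limma adjusted p on the y axis; the dashed line marks an adjusted p of 0.05. Red points are the 1665 genes higher in CGN and blue points the 2578 lower, with Il6 at 8.82 and Myh2 at -4.20 among the named genes.

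Skeletal muscle transcripts differed between the groups along with the inflammatory genes. The mean log2 value of the muscle list lay between 8.21 and 11.00 in controls and between 5.35 and 7.63 in CGN, a difference of -3.10 (exact permutation test, 2-sided, p = 0.0159, the smallest that 126 splits allow, run on 1 of the 34 lists after its values were seen). Of 20 measured muscle genes, 17 fell and 0 rose, and 19 fell adjusted over the list alone, among them Neb, a thin-filament protein (-2.98 ± 0.59). By a plain test without moderation 8 of the 20 passed, and Tnnc2, Tnni2, Myl11 and Myl1 did not (adjusted p = 0.0514 to 0.0556). The camera test gave an adjusted p of 4.70e-09, and adjusted p = 0.232 with an estimated correlation. When this muscle value entered limma as a covariate, chosen after the data were seen, 506 genes passed (439 higher, 67 lower), 450 of them at 2-fold (410 higher, 40 lower). That value correlated with group at -0.819 and made the variance of the group effect 3.04 times as large. Outside the muscle list, 379 of the 658 genes raised at least 2-fold still passed and 657 kept their sign, with a median log2 change of 1.64 before and 1.63 after and a median standard error of 0.201 before and 0.334 after. Of 509 genes lowered at least 2-fold, 30 still passed and 481 kept their sign, with medians of -1.29 and -0.95 and median standard errors of 0.243 and 0.375. Counts with this covariate are set beside list medians, since larger errors lower a count at the same change. Without CGN replicate 1, 798 genes were lower at 2-fold in place of 526.

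Many chemokine genes rose in CGN skin. Of 6 neutrophil-attracting CXC chemokines, 3 rose and 0 fell, with the same counts adjusted over the list alone. Beside Cxcl1 and Cxcl2 this was Cxcl3 (1.78 ± 0.43). Cxcl3 did not pass on its other probe set (0.11, adjusted p = 0.560), by the plain test (adjusted p = 0.0629) or with the muscle covariate (0.84 ± 0.69, adjusted p = 0.622), where 2 members of the list rose (median 1.25 without it, 0.87 with it). For that list camera gave an adjusted p of 1.21e-05, and adjusted p = 0.0627 with an estimated correlation. Of 17 other chemokines, 13 rose and 1 fell, or 14 and 1 adjusted over the list alone (camera adjusted p = 7.11e-11). In this list 7 rose and 0 fell with the muscle covariate (median 1.34 without it, 1.47 with it). The monocyte attractants Ccl7 and Ccl2 rose by 6.04 ± 0.23 and 5.87 ± 0.22, Ccl2 from a mean intensity of 215 to 12576, and Ccl20 rose by 5.21 ± 0.30 on a probe set that can bind related transcripts.

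Most measured cytokines and cytokine antagonists rose. Of 18 inflammatory cytokines, 10 rose and 1 fell, or 12 and 1 adjusted over the list alone (camera adjusted p = 3.88e-09). The counts were 5 and 0 with the muscle covariate (median 0.97 without it, 0.92 with it). Il1b, the fever-inducing interleukin, rose 60.1-fold (5.91 ± 0.25). Tnf was only slightly higher (0.58 ± 0.15, limma adjusted p = 0.0199), with overlapping groups and mean intensities of 10.2 and 15.3, and lost the call without control replicate 2 (adjusted p = 0.0508) or CGN replicate 4 (adjusted p = 0.0647), by the plain test (0.0606) and with the muscle covariate (0.86 ± 0.26, adjusted p = 0.137). Of 14 anti-inflammatory and decoy factors, 11 rose and 1 fell by both adjustments, and 5 and 0 with the muscle covariate (camera adjusted p = 7.84e-11), including Il10, which restrains macrophages (4.01 ± 0.19), and Zfp36, which destabilises cytokine mRNA (3.03 ± 0.14). Their median was 1.56, and 0.89 with the muscle covariate.

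Most genes of innate sensing and its signalling were higher in CGN skin. Of 21 sensor and inflammasome genes, 12 rose and 3 fell by both adjustments (camera adjusted p = 1.55e-06), led by the lectin receptor Clec4e (5.29 ± 0.23), the lipoprotein receptor Tlr2 (4.01 ± 0.19) and Irak2 (2.22 ± 0.13). All 16 measured NF-kB targets and feedback genes rose by both adjustments (camera adjusted p = 1.35e-23), with a median of 2.05, among them Nfkb2 (2.55 ± 0.11), Birc3 (2.91 ± 0.14) and the survival factor Bcl2a1 (4.37 ± 0.21). Of 17 STAT3 axis genes, 12 rose and 0 fell, or 13 and 0 adjusted over the list alone (camera adjusted p = 1.88e-12). They included the kinase Jak2 (2.17 ± 0.13), the receptor Il4r (2.05 ± 0.13) and Junb (2.05 ± 0.12). Of 29 immediate early genes, 24 rose and 1 fell, or 25 and 2 adjusted over the list alone (camera adjusted p = 7.23e-22), among them Fosl1 (4.97 ± 0.19) and Nr4a3 (3.81 ± 0.18). In the fit with the muscle covariate 9 sensor genes rose and 0 fell, and 16 immediate early genes rose and 0 fell. There 13 NF-kB genes rose and 0 fell (median 2.05 without it, 2.17 with it). Of the STAT3 axis genes, 8 rose and 0 fell in that fit (median 1.16 without it, 1.00 with it). The sensor median was 0.68 without the covariate and 0.64 with it, and the immediate early median 1.94 in both.

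**Figure D2:**
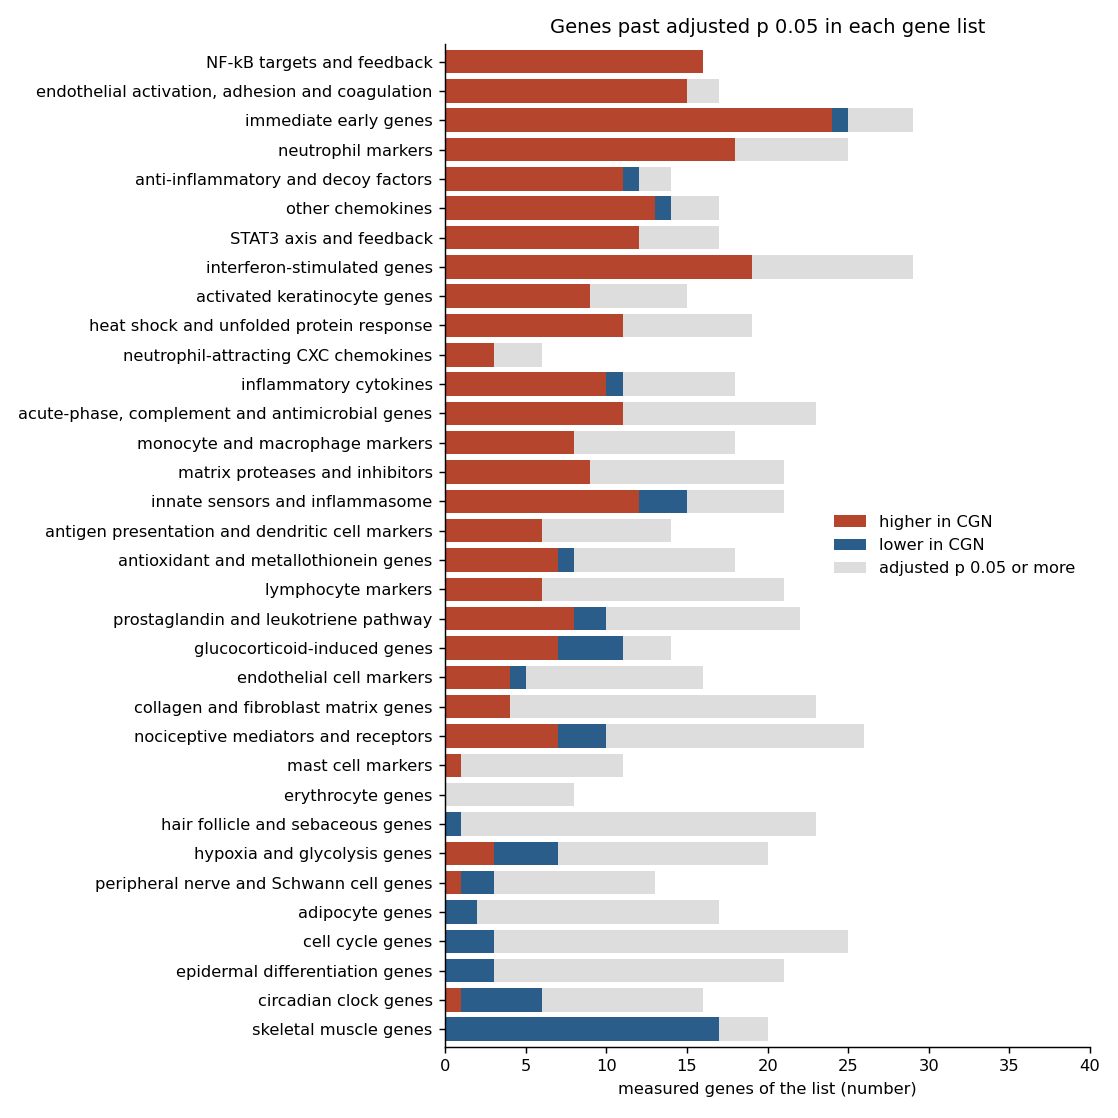
For each of the 34 gene lists, the bar gives the number of measured genes (x axis) that were higher in CGN (red), lower in CGN (blue) or at an adjusted p of 0.05 or more (grey). All 16 NF-kB genes are red, and 17 of 20 skeletal muscle genes are blue.

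Some genes of prostaglandin and leukotriene metabolism and of nociception changed, while most members of both lists did not pass the test. Of 22 prostaglandin and leukotriene genes, 8 rose and 2 fell, or 9 and 2 adjusted over the list alone, with a median of 0.02 and a mean of 0.63 (camera adjusted p = 0.00834; adjusted p = 0.141 with an estimated correlation). The inducible cyclooxygenase Ptgs2 rose 21.0-fold (4.39 ± 0.32), the prostaglandin E synthase Ptges 6.44-fold (2.69 ± 0.12) and the prostaglandin E receptor Ptger4 5.57-fold (2.48 ± 0.14), and 3 members rose and 0 fell with the muscle covariate (median 0.17). Dimmer probe sets gave smaller log2 changes, 0.99 for Ptgs2 and 0.53 and -0.04 for Ptger4, the last not past the test. The size of these 2 rises therefore depends on the probe set. Of 26 nociceptive mediators and receptors, 7 rose and 3 fell by both adjustments (camera adjusted p = 0.0380; adjusted p = 0.173 with an estimated correlation). The protease receptor F2rl1 rose by 1.70 ± 0.25 and the kinin receptor Bdkrb1 by 0.98 ± 0.18, whereas the neurotrophin Bdnf fell by 1.70 ± 0.13. Other probe sets of Bdnf (-0.27 and 0.01) did not pass. With the muscle covariate 2 nociceptive genes rose and 1 fell (median 0.12 without it, 0.10 with it), and F2rl1 did not pass (1.36 ± 0.43, adjusted p = 0.147). The capsaicin receptor Trpv1 differed by -0.11 (95% interval -0.31 to 0.09, adjusted p = 0.476) at mean intensities of 8.15 and 7.55, and no detection calls show whether these lie above background. The nociceptive count was 6 without control replicate 3, CGN replicate 3 or CGN replicate 4 and 5 without CGN replicate 2 or by the plain test. Its camera call was lost without control replicates 3, 4 or 5 or CGN replicates 3 or 4 (adjusted p = 0.0517, 0.0520, 0.0597, 0.0621 and 0.0651).

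**Figure D3:**
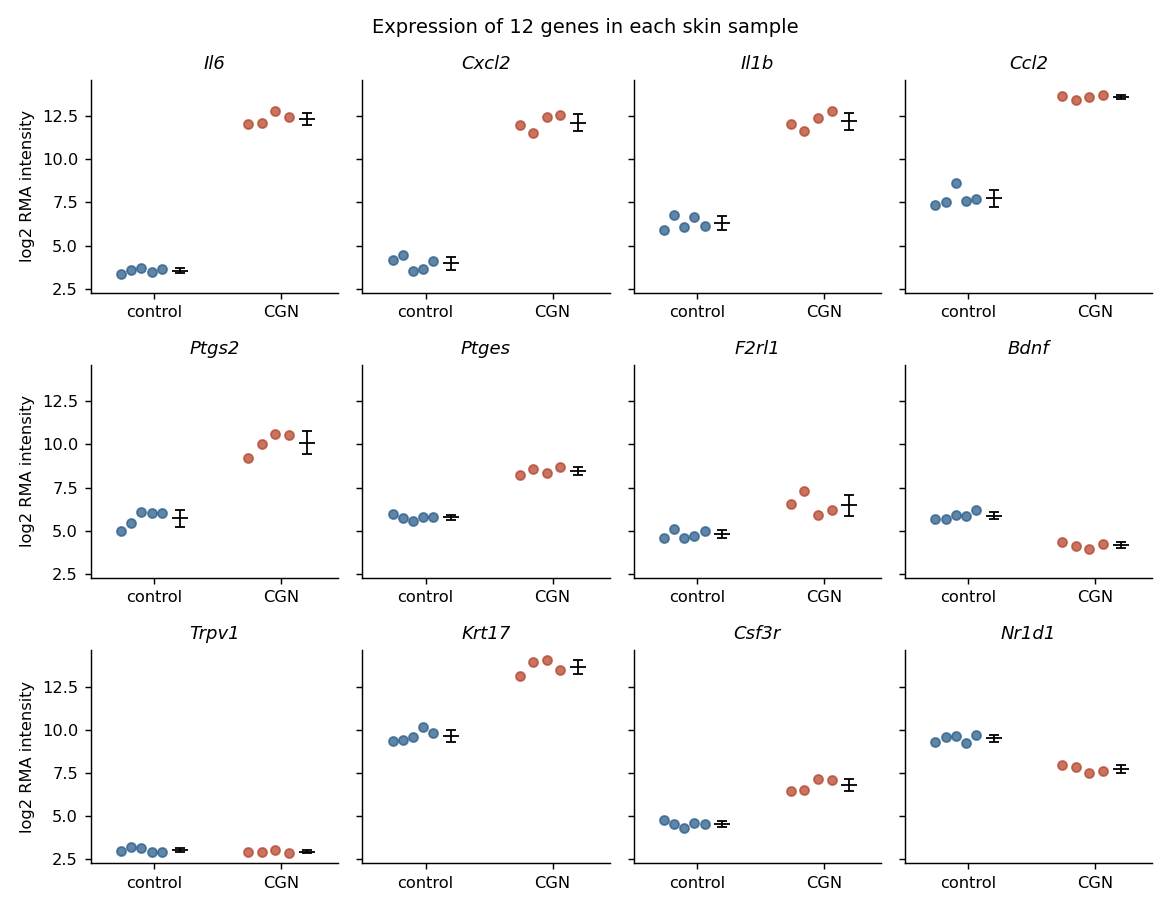
Each point is a skin sample (blue, 5 controls; red, 4 CGN), with the log2 RMA intensity on the y axis; the bar beside the points gives the mean and SD of the group. CGN samples lie above every control for Il6, Cxcl2, Il1b, Ccl2, Ptgs2, Ptges, F2rl1, Krt17 and Csf3r and below every control for Bdnf and Nr1d1, while Trpv1 differs by -0.11.

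Most genes of endothelial activation and some matrix proteases rose. Of 17 genes of endothelial activation, adhesion and coagulation, 15 rose and 0 fell by both adjustments, with a median of 2.51 (camera adjusted p = 7.84e-23), among them the protease Adamts1 (5.26 ± 0.19) and the matrix protein Thbs1 (5.10 ± 0.20). With the muscle covariate 14 of them rose and 0 fell, at a median of 2.83. Of 16 general endothelial markers, 4 rose and 1 fell by both adjustments (camera adjusted p = 0.320). The VEGF receptors Flt1 and Kdr rose by 1.47 ± 0.20 and 0.84 ± 0.16, and the tight junction gene Cldn5 fell by 0.90 ± 0.14. In this list 3 markers passed without control replicate 1 or 4 or CGN replicate 2, 3 or 4. In the fit with the muscle covariate the general endothelial list passed camera upward (adjusted p = 0.0268) while 0 of its members passed limma, 4 of them at an unadjusted p under 0.05 (median 0.03 without it, 0.17 with it). There Flt1 was at 1.37 ± 0.37, Kdr at 0.94 ± 0.29 and Cldn5 at -0.66 ± 0.23 (adjusted p = 0.0926, 0.138 and 0.187). Of 21 matrix proteases and inhibitors, 9 rose and 0 fell, or 12 and 0 adjusted over the list alone (camera adjusted p = 2.07e-08), including Mmp3 (2.93 ± 0.22) and Adamts4 (1.88 ± 0.12). With the muscle covariate 6 of this list rose and 0 fell (median 0.75 without it, 0.57 with it). Of 23 collagen and fibroblast genes, 4 rose by both adjustments, with the crosslinking enzyme Lox at 1.02 ± 0.16, Pdgfra at 0.68 ± 0.12 and fibronectin, Fn1, at 0.41 ± 0.09. Camera gave an adjusted p of 0.00628 for that list (adjusted p = 0.490 with an estimated correlation; 0.0597 without control replicate 5), and 7 members passed without CGN replicate 1. In the covariate fit 2 members passed (median 0.16 without it, 0.38 with it), and Lox was at 1.22 ± 0.29 (adjusted p = 0.0552).

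Some markers of several leukocyte types rose in CGN skin. Of 25 neutrophil markers, 18 rose and 0 fell by both adjustments, with a median of 1.28 (camera adjusted p = 7.39e-14). The G-CSF receptor Csf3r rose by 2.24 ± 0.16, the integrin Itgam by 1.49 ± 0.12 and the calcium-binding S100a8 by 1.67 ± 0.26. With the muscle covariate 11 neutrophil markers passed at a list median of 1.44, and S100a8 did not pass (1.72 ± 0.47, adjusted p = 0.0970). Of 18 monocyte and macrophage markers, 8 rose and 0 fell, or 9 and 0 adjusted over the list alone, with Ccr1 (3.49 ± 0.21), lysozyme Lyz2 (1.82 ± 0.15) and Ccr2 (1.34 ± 0.19) in front (camera adjusted p = 9.07e-06; adjusted p = 0.173 with an estimated correlation). In the fit with that covariate 2 of these passed (median 0.51 without it, 0.52 with it), and Ccr2 was at 1.46 ± 0.35 (adjusted p = 0.0607). Of 14 antigen presentation and dendritic cell markers, 6 rose by both adjustments, including Cd40 (1.36 ± 0.12), the Langerhans cell lectin Cd207 (1.37 ± 0.27) and Cd80 (0.44 ± 0.11) at mean intensities of 8.69 and 11.8. Camera gave an adjusted p of 0.000109 for it (adjusted p = 0.141 with an estimated correlation), and without CGN replicate 4 the count was 3 and Cd80 did not pass (adjusted p = 0.0575). The plain test also passed 3, and with the muscle covariate 1 passed (median 0.47 without it, 0.49 with it), with Cd207 at 0.76 ± 0.44 and Cd80 at 0.48 ± 0.21 (adjusted p = 0.437 and 0.289). Of 21 lymphocyte markers, 6 rose, or 7 adjusted over the list alone (camera adjusted p = 0.000135; adjusted p = 0.173 with an estimated correlation), with the cytotoxic gene Prf1 at 1.56 ± 0.23, Nkg7 at 0.71 ± 0.14 and Zap70 at 0.70 ± 0.14. None of the lymphocyte markers passed limma with the muscle covariate, 2 of them at an unadjusted p under 0.05 (median 0.26 without it, 0.16 with it). There Prf1 was at 1.69 ± 0.41, Nkg7 at 0.40 ± 0.23 and Zap70 at 0.40 ± 0.23 (adjusted p = 0.0654, 0.435 and 0.454). Of 11 mast cell markers, only Hdc, the histamine-forming enzyme, rose by both adjustments (2.99 ± 0.20; camera adjusted p = 0.106). Tpsab1 (0.47 ± 0.21, 95% interval 0.00 to 0.93) and Ms4a2 (-0.42 ± 0.23, 95% interval -0.93 to 0.08) did not pass, and without CGN replicate 1 the count was 2, with Tpsab1 past the test (adjusted p = 0.0486).

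Some members of the host defence and stress lists rose. Of 23 acute-phase, complement and antimicrobial genes, 11 rose and 0 fell, or 12 and 0 adjusted over the list alone (camera adjusted p = 3.88e-09), among them complement C3 (4.32 ± 0.23) and the protease inhibitor Slpi (4.21 ± 0.36). Of 29 interferon-stimulated genes, 19 rose and 0 fell, or 21 and 0 adjusted over the list alone, with a median of 1.14 and with Ifit3 (6.10 ± 0.40), Oasl (4.24 ± 0.30) and Gbp5 (1.74 ± 0.14) in front (camera adjusted p = 2.11e-11; adjusted p = 0.116 with an estimated correlation). Of 18 antioxidant and metallothionein genes, 7 rose and 1 fell by both adjustments, including Sod2 (2.96 ± 0.14), Txnrd1 (1.60 ± 0.13) and Gpx2 (1.71 ± 0.18) (camera adjusted p = 0.000328; adjusted p = 0.0752 with an estimated correlation). Of 19 heat shock and unfolded protein genes, 11 rose, or 12 adjusted over the list alone (camera adjusted p = 1.65e-06; adjusted p = 0.127 with an estimated correlation), with the chaperones Dnaja1 (1.43 ± 0.14), Dnajb1 (1.21 ± 0.15) and Hsp90aa1 (1.11 ± 0.16). In the fit with the muscle covariate 7 acute-phase genes passed at a list median of 1.29 (0.54 without it), with 17 at an unadjusted p under 0.05 (13 without it). In that fit 8 interferon-stimulated genes passed at a list median of 1.16 and 4 antioxidant genes at 0.27 (0.36 without it). There 1 heat shock gene passed (median 0.56 without the covariate, 0.36 with it), with Dnajb1 at 1.04 ± 0.26 and Hsp90aa1 at 0.88 ± 0.28 (adjusted p = 0.0728 and 0.148).

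Glucocorticoid-induced and hypoxia genes moved in both directions, and several clock genes fell. Of 14 glucocorticoid-induced genes, 7 rose and 4 fell by both adjustments (camera adjusted p = 0.00938; adjusted p = 0.246 with an estimated correlation), with rises of Cebpd (3.48 ± 0.17), Angptl4 (2.91 ± 0.23) and Nfil3 (2.21 ± 0.17). Of 16 circadian clock genes, 1 rose and 5 fell, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.106). The repressor Nr1d1 fell by 1.78 ± 0.13, the output factor Dbp by 2.09 ± 0.26 and Cry2 by 1.25 ± 0.20. The labels used here give no time of day. The other probe set of Cry2 was at 0.0029 and did not pass. With the muscle covariate Nr1d1 alone of the clock list passed (-1.71 ± 0.24; list median -0.18 without it, -0.17 with it), with Dbp at -1.59 ± 0.42 and Cry2 at -0.59 ± 0.27 (adjusted p = 0.0884 and 0.315). Of 20 hypoxia and glycolysis genes, 3 rose and 4 fell, or 5 and 4 adjusted over the list alone (camera adjusted p = 0.414). The vasodilator peptide Adm rose by 5.18 ± 0.23 and Hif1a by 0.87 ± 0.12, and Ankrd37 fell by 0.90 ± 0.15. In the fit with the muscle covariate 1 hypoxia gene rose and 1 fell, with Hif1a at 0.70 ± 0.20 (adjusted p = 0.116), and 6 glucocorticoid-induced genes rose and 0 fell. The hypoxia median was 0.040 without the covariate and -0.010 with it, and the glucocorticoid median 0.66 and 0.78.

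Most keratinocyte activation genes rose, while few genes of epidermal differentiation passed the test. Of 15 activated keratinocyte genes, 9 rose and 0 fell, or 11 and 1 adjusted over the list alone (camera adjusted p = 3.54e-10; adjusted p = 0.0520 with an estimated correlation). The stress keratin Krt17 rose 15.9-fold from a mean intensity of 801 to 12761, and the EGF family ligand Epgn rose by 4.23 ± 0.25. In this list 5 members passed with the muscle covariate (median 0.88 without it, 0.71 with it). Of 21 epidermal differentiation genes, 3 fell and 0 rose, and 0 passed adjusted over the list alone; the median was -0.45 (camera adjusted p = 0.00647; adjusted p = 0.463 with an estimated correlation). These were the keratin Krt2 (-0.45 ± 0.13), the basal-layer factor Tp63 (-0.60 ± 0.19) and the transglutaminase Tgm3 (-0.63 ± 0.20), each of which lost its call in 7 of the 9 fits that left out a sample (adjusted p between 0.0551 and 0.133). The epidermal count was 0 without control replicate 2, 4 or 5 or CGN replicate 4, 1 without control replicate 1 or CGN replicate 3, 5 without CGN replicate 1 and 10 without control replicate 3. It was 8 with array weights, 0 by the plain test and 0 in limma with the muscle covariate, where 7 members had an unadjusted p under 0.05 and the median was -0.60. Of 25 cell cycle genes, 3 fell and 0 rose, or 1 adjusted over the list alone (camera adjusted p = 0.0289; adjusted p = 0.648 with an estimated correlation): Ccnd1 (-0.71 ± 0.16), Mcm7 (-0.61 ± 0.18) and Aurkb (-0.97 ± 0.31), the last with another probe set of opposite sign (0.11, not past the test). Mcm7 and Aurkb each lost the call in 7 of the 9 such fits (adjusted p between 0.05005 and 0.129). The cell cycle count was 10 without CGN replicate 3 and 1 without control replicate 2, 4 or 5 or CGN replicate 2 or 4. Its camera call was lost without control replicate 2 or 3 or CGN replicate 2 or 4 (adjusted p = 0.0663, 0.0676, 0.171 and 0.193), and without the dimmest 30% of genes (adjusted p = 0.109). With array weights 6 cell cycle genes passed, by the plain test 1, and in limma with the muscle covariate 0, where 2 had an unadjusted p under 0.05 (median -0.45 without it, -0.73 with it).

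Hair follicle, fat, nerve and red cell lists did not pass camera. Of 23 hair follicle and sebaceous genes, 1 fell and 0 passed adjusted over the list alone, with a median of 0.02, a mean of -0.07 and an upward camera direction (camera adjusted p = 0.650). That gene, the hair regulator Hoxc13 (-0.87 ± 0.25), passed with all samples but in only 2 of the 9 fits that left out a sample, those without control replicate 3 or CGN replicate 1 (adjusted p up to 0.0720 in the others). Msx2 (-0.34 ± 0.13, 95% interval -0.62 to -0.06) and Krt33b (0.32 ± 0.13, 95% interval 0.02 to 0.61) did not pass. Without CGN replicate 4 Msx2 passed (adjusted p = 0.0327), and without CGN replicate 1 the count was 2. Of 17 adipocyte genes, 2 fell, or 1 adjusted over the list alone (camera adjusted p = 0.650), namely the acyl-CoA synthetase Acsl1 (-1.14 ± 0.21) and Cebpa (-0.46 ± 0.14). The complement factor Cfd was at 1.13 ± 0.46 (adjusted p = 0.114), and past the test without CGN replicate 1 (adjusted p = 0.0486). The adipocyte count was 1 without control replicate 2, 4 or 5 or CGN replicate 3 or 4, and 4 without CGN replicate 1. Cebpa did not pass in the first 5 of these fits (adjusted p between 0.0745 and 0.106). Of 13 nerve and Schwann cell genes, 1 rose and 2 fell by both adjustments (camera adjusted p = 0.698): Gfap was at 0.59 ± 0.15, Prx at -0.68 ± 0.18 and the myelin gene Mbp at -0.93 ± 0.27. Other probe sets of Prx and Mbp had the opposite sign without passing. Gfap did not pass without CGN replicate 2 or 4 (adjusted p = 0.0543 and 0.05001), Prx without CGN replicate 4 (0.0611), and Mbp without control replicate 1 or 3 or CGN replicate 2, 3 or 4 (0.0532 to 0.0901), and the count was 1 without CGN replicate 2 and 0 without CGN replicate 4. In limma with the muscle covariate 0 members of the hair follicle, adipocyte and nerve lists passed, with 1, 5 and 1 at an unadjusted p under 0.05 and medians of 0.050, 0.14 and -0.019, and the plain test passed 0, 1 and 0. Of 8 erythrocyte genes, 0 passed the limma test, 0 at an unadjusted p under 0.05 and 0 by the plain test (median -0.01, upward camera direction, camera adjusted p = 0.938), among them Epor (-0.25), Epb42 (0.15) and Ahsp (0.03).

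**Figure D4:**
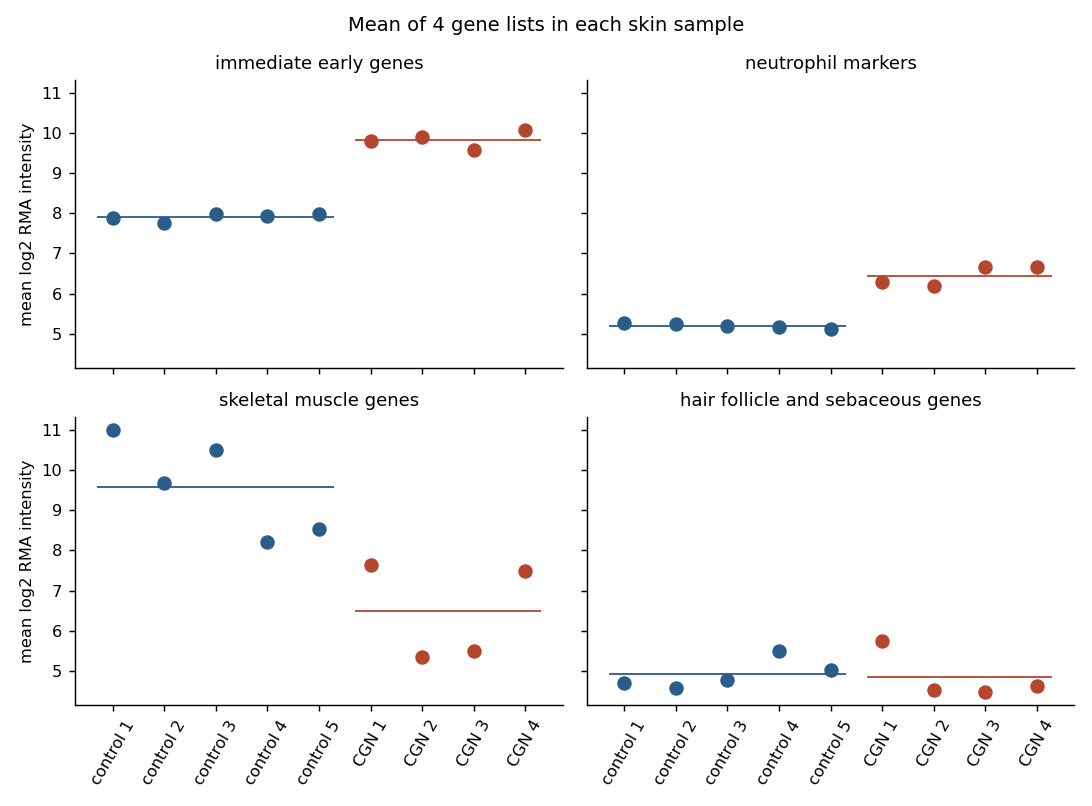
Each point is the mean log2 RMA intensity (y axis) of a gene list in a sample (x axis; blue, control; red, CGN), and the lines are group means. Skeletal muscle means run from 8.21 to 11.00 in controls and from 5.35 to 7.63 in CGN, and CGN replicate 1 has the highest hair follicle mean of its group at 5.75.

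Across the lists, 26 of 34 passed camera, 23 upward and 3 downward (epidermal differentiation, skeletal muscle and cell cycle). With an estimated correlation 11 passed, all upward: other chemokines, inflammatory cytokines, anti-inflammatory factors, innate sensors, NF-kB, STAT3, immediate early, endothelial activation, neutrophil, acute-phase and matrix protease genes. Their camera adjusted p then lay between 0.00357 (NF-kB) and 0.0432 (acute-phase), far above the values at the preset correlation.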

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

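The tests of muscle content and of a swapped sample, and the fit with a muscle covariate, were chosen only after the result was seen.

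Samples far from the others of their group were searched for in 292 groups of 4 or 5 values, and 15 values stood apart, where about 14.6 are expected by chance at 1 in 20. In log2 intensity, control replicate 2 was lowest for Tnfaip6 (3.68) and Lyz2 (11.86), control replicate 1 was highest for C3 (4.62) and lowest for Tp63 (11.33), and control replicate 3 was lowest for Tgm3 (11.94). CGN replicate 2 was lowest for Cxcl1 (11.34) and Cd80 (3.29) and highest for Epgn (8.69). CGN replicate 4 was highest for Adamts1 (12.54) and Adamts4 (6.19), CGN replicate 3 lowest for Mbp (8.17) and CGN replicate 1 lowest for Hif1a (11.90). The lymphocyte list mean was highest in CGN replicate 3 (4.89). Among probe sets with no gene name, outside the gene tests, 883 of 16178 passed limma's adjusted p, 355 higher and 528 lower in CGN.

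CGN replicate 1 stood apart on the first component of all genes, at 20.8 against 53.7 to 55.1 in the other CGN samples, and in the mean of the hair follicle list, at 5.75 against 4.47 to 4.61. A label swapped with a control is argued against, since CGN replicate 1 held a median share of 0.613 of the rise of the 30 most raised genes on the linear scale. Dilution with less inflamed tissue predicts 1 common share under 0.8, and the median was 0.575 for the other raised genes, a difference of 0.0386, and 0.535 for lowered genes outside the muscle list. In CGN replicates 2, 3 and 4 that difference was -0.196, -0.0238 and 0.132, with shares of 0.733, 0.969 and 1.29 for the 30 most raised genes, so that CGN replicate 1 alone had both a low share and a small difference. Similar medians do not show 1 common share. In CGN replicate 1 the interquartile range was 0.38871 to 0.80033 for the other raised genes and 0.49472 to 0.81734 for the 30 most raised. Il6 was at 0.7447, Il1b at 0.803 and Cxcl1 at 1.1551. The other raised genes also spread widely in CGN replicate 2 (0.66468 to 1.2656), so this spread cannot decide on dilution. In mean log2 value, the NF-kB list of CGN replicate 1 was at 9.04, against 9.01 to 9.28 in the other CGN samples. Its immediate early list was at 9.798, against 9.572 to 10.073. Most of the other lists that passed camera upward were lowest in CGN replicate 1 among the CGN samples. Among them were anti-inflammatory factors (8.62 against 8.94 to 9.08) and activated keratinocyte genes (8.39 against 8.79 to 9.09). Dilution by itself would lower the NF-kB and immediate early means too, so it may account for part of the pattern at most. A weaker response of that animal, which could give the same shares, was not tested and stays open.

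Skeletal muscle genes were lower in every CGN sample than in every control, by at least 0.579 in the mean log2 value. Within groups, where treatment does not differ, 1 factor per sample explained 86.1% of the variance of the muscle list (median 44.7% and highest 94.5% in 1000 random lists matched on mean), as uneven amounts of muscle in the skin pieces would give. From lowest to highest sample the muscle mean differed 6.92-fold among controls and 4.86-fold among CGN samples. A loss of muscle transcripts caused by carrageenan and pieces of CGN skin taken with less muscle cannot be told apart, because the muscle value follows the group. A chance difference between 4 and 5 pieces also stays open: the exact permutation p of 0.0159 is fixed at the smallest value that the samples allow once the groups do not overlap, and it was run on 1 of 34 lists.

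The number of changed genes was set against 100 of the 126 splits of the 9 samples into 4 and 5, the real split included. The 4243 changed genes and the 1184 changed at least 2-fold were each reached in 1 split, the real one, with 0 genes in the highest other split. Mixed splits carry the group difference as spread within their groups, which lowers their counts. Being the only such split among 100 argues against chance but cannot exclude it. For the 26 shifted lists chance cannot be excluded by this count. Only 2 splits were as large, but the highest other split gave 27 lists and 24 of the 99 other splits gave at least 20. The split with 27 lists held CGN replicates 2, 3 and 4 with control replicate 3, so it still carried most of the group difference. Such splits do not measure chance alone, and the number of lists cannot decide the question.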

How the results depend on the processing

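The fits with the muscle value as a covariate, with symbols as deposited, without _x_at and _s_at probe sets and with a block by column number were chosen only after the result was seen. Under quantile normalization, median centring, the omission of dim genes or of _x_at and _s_at probe sets, the mean of a gene's probe sets, limma's trend and robust options, array weights, symbols as deposited and the plain test, the counts of changed genes stayed within 1.5 times those reported, from 3168 (plain test) to 5062 (array weights). When all 43685 probe sets were tested, 5545 probe sets passed, a count that cannot be set against one of 19100 genes. Of the values of named genes under the alternatives, 2246 kept their sign and side of the threshold, 147 lost the call, 3 gained it and 11 changed sign. The cause was not tested except where stated. Fits that left out a sample gave 3108 to 4906 changed genes and 1016 to 1534 at 2-fold; those lower at 2-fold ranged from 393 to 798 (798 without CGN replicate 1). The other deposited table was not run as an alternative, since its values were identical.

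No pairing by replicate number was seen: same-numbered CGN and control samples correlated at -0.280, 0.044, 0.007 and -0.121 in their deviations, across genes. Differently numbered pairs ran from -0.294 to 0.346, so these values cannot exclude a pairing. By its column name CGN replicate 4 is number 5, and it correlated at -0.294 with control replicate 5. With a replicate block over the 8 samples numbered in both groups, 2603 genes passed (1170 higher, 1433 lower), against 3475 in those samples without a block; fewer samples and residual degrees of freedom enter this fit. With a block by the column numbers it was 2788 (1576 lower). Ahsp, past the test in no fit, had a log2 change of -0.0569 in the block fit and in the same 8 samples without it, -0.0419 with the column block, and -0.13 to 0.22 when a sample was left out. The erythrocyte list turned to a downward camera direction in these fits (adjusted p = 0.663, 0.715 and 0.695), with symbols as deposited (0.793), and in 5 of the fits without a sample (0.496 to 0.979 over all 9 such fits).

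With the muscle value as a covariate 506 genes passed (439 higher, 67 lower), 450 at 2-fold (410 higher, 40 lower), so that 86.8% of changed genes were higher against 39.2% in the fit reported; 132 list members passed against 297. The covariate shares most of its variation with the group, which widens the errors, and it is built from the muscle genes, so their values with it are void as a test: Tnnc2 0.0525, Tnni2 0.17, Myl11 0.11, Myl1 0.13, and camera adjusted p = 0.697 for the muscle list. The Schwann cell list turned upward with the covariate (camera adjusted p = 0.704) and with array weights (0.946), and the hair follicle list downward without CGN replicate 1 (0.435; 0.202 to 0.881 over the fits without a sample).

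Camera with an estimated correlation called 11 lists (11 upward, 0 downward). A 1.5-fold threshold gave 2640 genes (1127 higher, 1513 lower) and limma's treat against 1.5-fold 593 (137 lower). With no detection calls, signal over background is unknown, so rises from low control levels are not exact. Of the named genes, 17 rose from a control mean below 16.7, the lowest median of an array, among them Il6 (11.6), Cxcl2 (15.7), Tnfaip6 (16.1), Areg (9.89), Il24 (15.5), Clec4e (9.65), C3 (15.3), Epgn (11.2) and Il10 (10.8).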

Other observations

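The test of a neutrophil source and the test of FoxO targets were planned before their results were seen; the genes outside the lists were chosen after their values were seen, and so was the fit with a muscle covariate.

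Among genes on no list, large rises that also passed limma with the muscle covariate included the protease inhibitor Tfpi2 (5.65 ± 0.32), the small GTPase Rnd1 (4.92 ± 0.12), the amino acid transporter Slc6a14 (4.88 ± 0.36, from a low control mean of 10.4), the ficolin Fcnb (4.66 ± 0.24), the scramblase Plscr1 (4.50 ± 0.28), the endothelial gene Apold1 (4.42 ± 0.30), the platelet and leukocyte substrate Plek (4.15 ± 0.17) and the natriuretic peptide Nppb (3.70 ± 0.31). Rnd1 rose from a mean intensity of 41.6 to 1255. Falls that passed both fits were smaller: the transcription factor Tbx1 (-3.11 ± 0.30), Pik3ip1, an inhibitor of PI3 kinase (-2.56 ± 0.25), the linker histone H1f1 (-1.68 ± 0.16), Klf15 (-1.52 ± 0.13), Pias3, an inhibitor of STAT3 (-1.45 ± 0.14), and the homeobox gene Irx5 (-1.12 ± 0.12). Tbx1 fell from a mean intensity of 1781 to 206, and by 2.55 on the log2 scale with the covariate.

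Neutrophil RNA may account for the rise of neutrophil markers. Of 11 transcripts chosen as largely restricted to neutrophils and other myeloid cells, 10 rose and the median change was 1.495, where a median under 0.3 would have argued against it. Among the brighter probe sets, which cannot be ranked against each other, Il1r2 was at a mean intensity of 407 in controls and 991 in CGN, Trem1 at 59.8 and 412 and Ncf1 at 84.8 and 251. In untreated skin Il1r2 thus lay far above the medians of the control arrays (16.7 to 17.81), and the cells that held it were not identified. Il1r2 is also on the anti-inflammatory list and Mmp8 on the protease list, and Fpr1 did not pass (0.08 ± 0.09) at 7.59 and 8.01. A rise of these transcripts in cells already in the skin was not tested and stays open.

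A shared fall of FoxO target genes was tested as a hypothesis because Pik3ip1 and Sesn1 were among the falls. Of 15 other genes on the target list, 7 fell and 1 rose, with a median of -0.241, between the bounds set for either answer. This list includes the factors Foxo1, Foxo3 and Foxo4 themselves. Foxo1 was among the falls (-0.66 ± 0.18), and the median is the value of Foxo4. With the muscle covariate the median was -0.237 and Klf15 alone fell. The largest fall was Ccng2 (-1.71 ± 0.22) and the only rise Gadd45a (2.05 ± 0.19), and camera gave an unadjusted p of 0.0971, or 0.216 with an estimated correlation, so the test did not decide.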
